A study of Arabidopsis thaliana with 6 samples.

How the data were processed

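Total RNA of Arabidopsis seedlings was labelled with biotin and hybridised to Affymetrix ATH1 arrays, 1 array for each of 6 samples, per the labels. The deposited value of each probe set is an intensity on a linear scale. The method by which the authors summarised the probes is not given in the sources used here. From the values, each array had been scaled to a common 2% trimmed mean of 100.01, no value was negative, 126 values were 0 and the arrays' maxima lay between 3662.5 and 5060.

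Groups were taken from the strain labels, with control (aeq+) replicates 1 and 2, cdpk6-yfp line 4 replicates 1 and 2, and cdpk6-yfp line 1 with 1 array. The title of 1 array, with Kan-3, follows those of the control arrays, with Kan-1 and Kan-2. Its source name also gives the control, while its strain label calls it line 1. The code in its title, A3-1, goes with that of the line 1 array, A3-2, as A1-1 and A1-2 mark the controls and A2-1 and A2-2 line 4. It was placed in no group, and the fits with it as control and as line 1 were fixed beforehand as alternatives. The design text speaks of 2 biological replicates of pools of about 40 plants. Nothing says whether pools were grown or harvested on separate occasions, so p-values measure the spread between these pools only. The number of arrays limits the precision of every difference.

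Deposited values of 0 were raised to the smallest positive value, 0.1, and all values were taken to log2 with no further scaling between arrays, since the trimmed means lay within 5% of each other. Of 22810 probe sets, 64 control probe sets were left out, and of the other 22746 the lowest 40% by mean log2 value over the 5 grouped arrays were left out, which kept 13647. Fits used lmFit and eBayes with a variance trend in limma 3.58.1 (R 4.3.3) and Benjamini-Hochberg adjustment over the probe sets kept, with a threshold of 0.05. Line 4 was compared with the control in a fit of 5 arrays in 3 groups (2 residual degrees of freedom), and both cdpk6-yfp lines together were compared with the control in a fit of the same arrays in 2 groups (3 residual degrees of freedom). Line 1 was described by its difference from the control mean, and limma tests of it were run among the alternatives only. Where a single array is compared in limma, it is assumed to vary like the other groups. The correlation of both lines' differences was set beside 100 simulated draws of unchanged groups, with controls drawn anew and shared by both lines. The side of line 1 at the line 4 changes over 2-fold was set beside 100 draws with shared controls, line 1 unchanged and line 4 changed where called. Opposite sides were set beside 100 further draws with line 4 unchanged, changed where called or changed everywhere.

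Probe sets were named from the platform annotation provided with the series. Of 22746 probe sets, 13513 had 1 gene, 503 several and 8730 none in that table, and of the 13647 kept these numbers were 7362, 281 and 6004. Symbols of 13436 probe sets were updated through the gene table of the TAIR10.1 assembly, and 77 kept the older symbol. That table served for names only, and no coordinates are printed because the files name no genome build. An unnamed probe set is not a probe set without a gene. No probe set named as CPK3 or CPK6 was in the table, so the CDPK6 transcript was not analysed here.

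Genes named in the text follow a rule set before the data were examined. For line 4 and for both lines together these are the 12 largest rises and 12 largest falls among probe sets of 1 gene that passed with every transgenic array on the same side of both controls. Where fewer passed, the smallest p-values fill the list and the genes are described as not passing. For line 1 these are the 6 largest differences in each direction outside both controls, and for each gene list up to 4 members with the smallest p. STZ, EXPA4 and XTH16, which complete their lists, and the clock genes of the closing observations were named beside these. The 26 gene lists held 482 loci, of which 63 were named on the array and 43 measured. At least 3 measured members were needed for a list test, which left 7 lists. There were 8 lists with 1 or 2 measured members and 11 with none, which were the CPK family, ABA and dehydration response, jasmonate, brassinosteroid, cytokinin, seed storage, shoot meristem and flower, cell cycle, phosphate starvation, reactive oxygen metabolism, and sugar starvation and senescence. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. For line 1 a list's median was placed among 10000 random lists matched on mean expression.

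Fits were tested on simulated data of 13647 probe sets with 200 changed. For line 4 against the control, 77% of 2-fold and 100% of 4-fold changes were recovered with 6 false calls. For both lines against the control these were 82%, 100% and 6, and for the single line 1 array 62%, 98% and 10. The simulated spreads came from the fit of 3 groups, and both lines were given the same change with no other difference between them. In the measured fit of both lines the difference between the lines is part of the error. The 82% and 100% therefore do not tell how many shared changes that fit could find. With no change simulated, 0 probe sets were called for line 4. Alternatives were quantile normalization, equal array medians, no filter, a filter at 60%, a pseudocount equal to the value at the 20th percentile (10.3), no variance trend, each reading of the conflicting array, each replicate left out, the replicate number as a block, the 4 arrays of line 4 and control alone, and the mean of both lines in the fit of 3 groups. Figures were drawn with matplotlib 3.10.9.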

Results

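The series profiled transcripts of Arabidopsis seedlings in order to ask what CDPK6, a calcium-dependent protein kinase, does in development, as its title puts it. Expression was measured on 6 ATH1 arrays, each hybridised with RNA from a pool of about 40 plants grown at 22 °C with 16 h of light a day. The labels place 2 arrays in a control line called aeq+, 2 in a cdpk6-yfp line numbered 4 and 1 in a cdpk6-yfp line numbered 1. On 1 further array the title is numbered after the control arrays (Kan-3) and the source name gives the control, while the strain label gives cdpk6-yfp line 1. The code in its title, A3-1, goes with that of the line 1 array, A3-2. The array with these conflicting labels was placed in no group, and it enters a value below only where it is named. The median deposited intensity was 44.2 and 46.4 on the control arrays, 44.7 on each line 4 array and 44.7 on the line 1 array. Replicates correlated at r = 0.983 for the control and r = 0.990 for line 4 across 13647 probe sets, which are not independent of each other, whereas line 4 correlated with the control arrays at 0.951 to 0.954 and line 1 at 0.936 to 0.942. Scanner background averaged 142.62 on control replicate 2 and between 89.78 and 93.79 on the other 4 arrays compared. The probe set for 25S ribosomal RNA read 282.1 and 277.2 on the control arrays, 275.4 and 915.9 on the line 4 arrays and 1073.1 on the line 1 array. The ratio of 3′ to 5′ probe signal, which rises as RNA degrades, was 4.27 and 4.30 for actin on the control arrays, 3.19 and 3.48 in line 4 and 4.17 in line 1, and for GAPDH 1.79 and 1.71, 1.54 and 1.43, and 1.58. The level of the CDPK6 transcript itself was not analysed here, because no probe set used here was named as either gene that carries or has carried that name (CPK3, AT4G23650, and CPK6, AT2G17290).

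The comparison of line 4 with the control asked which transcripts differed in a line that carries cdpk6-yfp. AT5G03350, a legume-type lectin, stood at 1330.7 and 1385.1 intensity units in line 4 and at 59.0 and 58.4 in the control, a log2 difference of +4.53 ± 0.08 (SE, n = 2 against 2, limma adjusted p = 2.76e-09). CHI, which encodes a chitinase, rose by 2.71 ± 0.12 (adjusted p = 1.24e-06), RING1, a RING-type ubiquitin ligase, by 2.62 ± 0.12 (1.48e-06) and AT5G52810 (SARD4), which acts in the synthesis of the immune signal pipecolate, by 2.59 ± 0.16 (1.08e-05). The calmodulin-like gene AT2G41090 (CML10) rose by 2.89 ± 0.09 and the leucine-rich repeat receptor kinase gene AT1G35710 by 2.90 ± 0.15. Further rises were 4.01 ± 0.13 for AT5G52760, which encodes a heavy-metal-associated domain protein, 3.83 ± 0.20 for AT3G60420 of the phosphoglycerate mutase family, 3.16 ± 0.13 and 2.59 ± 0.21 for the AAA-type ATPase genes AT1G43910 and AT5G17760, and 2.40 ± 0.09 for AT2G25510. AT3G25150 rose by 4.46 ± 0.52, but its control values of 11.1 and 2.6 lay near the floor of the array, and with a pseudocount of 10.3 intensity units the difference was 2.95.

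Named falls in line 4 were smaller. AT4G39675 and AT1G33055 fell by 2.23 ± 0.19 and 2.22 ± 0.14 (SE, adjusted p = 9.02e-05 and 1.40e-05), and AT1G21480, an exostosin family gene, fell by 2.15 ± 0.47 (adjusted p = 0.0154) with line 4 values of 39.2 and 10.4. The glutaredoxin genes AT3G62950 and AT4G15690 fell by 1.53 and 1.45. AT1G10640 and AT1G57590, which encode a pectin-lyase-like protein and a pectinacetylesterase, fell by 1.39 and 1.33, and the protein phosphatase 2C gene AT3G05640 fell by 1.25. AT4G27657, AT5G03230, AT1G48330 and AT3G20340 completed the 12 named falls, at -1.34, -1.31, -1.26 and -1.24. All 24 of these genes had both line 4 arrays outside the range of the control arrays, as the naming rule requires. The same held at all 2111 probe sets that passed and at 8207 of all 13647, where 100 simulations with line 4 unchanged gave 4551 on average. With the array of conflicting labels counted as control, 10 of the 12 falls and 4 of the 12 rises kept their direction but no longer passed, and 1 fall, AT4G27657, turned from -1.34 ± 0.16 to 0.066 ± 1.32. Some of these differences grew while their SE grew more, from 4.01 ± 0.13 to 5.05 ± 0.97 for AT5G52760, from 3.83 ± 0.20 to 4.85 ± 0.97 for AT3G60420, from -2.23 ± 0.19 to -2.89 ± 0.64 for AT4G39675 and from -1.31 ± 0.11 to -1.59 ± 0.28 for AT5G03230. Others shrank, such as AT4G15690 from -1.45 ± 0.19 to -0.75 ± 0.68, and the median of the 12 falls went from -1.37 to -1.14. With it counted as line 1, 10 of the falls and 1 of the rises no longer passed, although by construction no difference changed, since the median SE of the falls grew from 0.18 to 0.36. AT1G21480 also failed to pass without either control replicate (adjusted p = 0.0597 and 0.0671), with no filter on dim probe sets (0.0980) and without a trend in the variance (0.0840). AT1G48330 failed without line 4 replicate 2 (0.0529) and with no filter (0.0627), and AT1G57590 with no filter (0.0542).

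**Figure D1:**
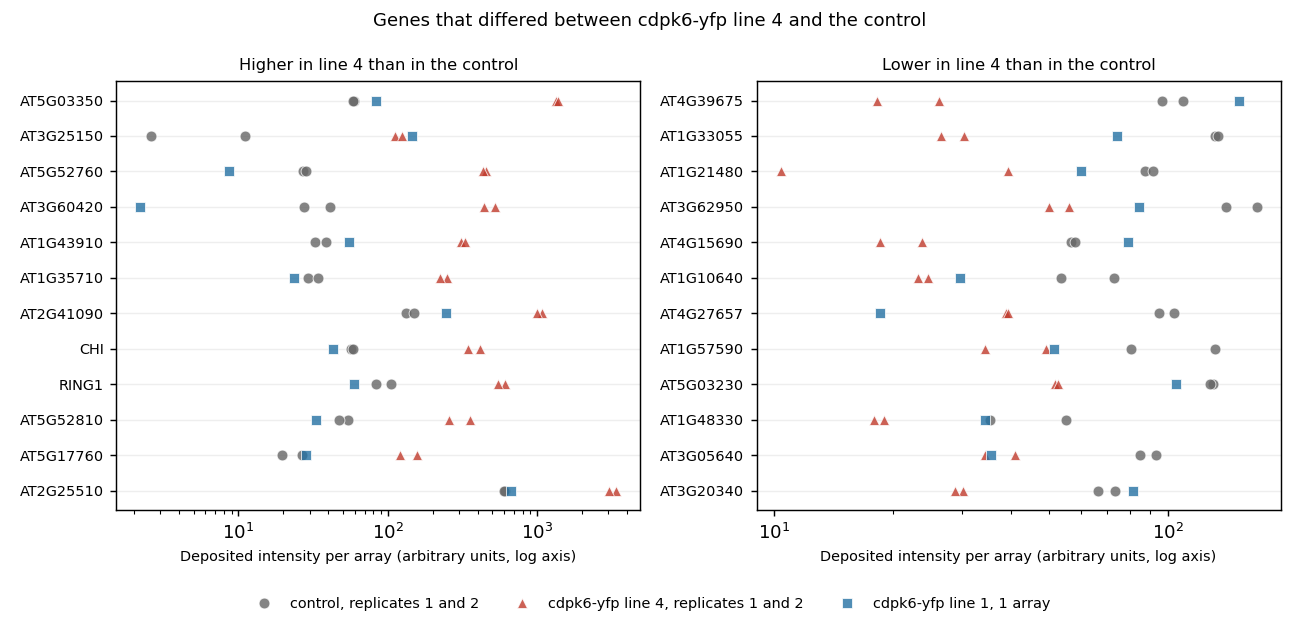
Deposited intensity on a log axis for the 12 genes named as higher and the 12 named as lower in line 4, with a circle for each control array, a triangle for each line 4 array and a square for the line 1 array. Line 1 lies with line 4 for AT3G25150 (144.4 units) and far from it for AT3G60420 (2.2 units).

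In all, 2111 of 13647 probe sets passed an adjusted p of 0.05 in limma, 1105 higher and 1006 lower in line 4. Beyond 2-fold the balance was 220 rises against 77 falls, and beyond 8-fold 23 rises against 0 falls. At an unadjusted p under 0.05 there were 4132 probe sets. Of the 220 rises over 2-fold, 104 matched 1 gene, 1 matched several and 115 carried no gene name here, and the largest rise of all, 6.57 on the log2 scale, was of an unnamed probe set. The count depended on the array with conflicting labels, standing at 88 when it was added to the control and at 183 when it was added to line 1. It was 1058 without line 4 replicate 1, 1026 without line 4 replicate 2, 1256 with no filter on dim probe sets and 1116 without a trend in the variance.

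Of the gene lists fixed before the data were examined, cold response was the 1 that passed a list test in line 4. COR15A and COR15B, which encode cryoprotective chloroplast proteins, fell by 1.19 ± 0.19 and 1.15 ± 0.16 (SE, adjusted p = 0.00314 and 0.00155), and the dehydrin gene COR47 fell by 0.50 ± 0.10 (adjusted p = 0.00835). The other 2 of its 5 measured members, LTI30 and STZ, differed by -0.27 and -0.21 and did not pass over all probe sets, while all 5 passed when adjusted over the list alone. Among 7 lists tested with camera, cold response had an adjusted p of 0.00236 with a preset correlation of 0.01. It did not pass in fry (adjusted p = 0.295) or in camera with an estimated correlation (adjusted p = 0.907). All 7 lists had this 0.907, at estimated correlations from -0.23 to 0.88. With 2 residual degrees of freedom the latter test could not tell the lists apart, so it cannot decide. Its median of -0.50 turned to 0.50 with the array of conflicting labels as control (adjusted p = 0.524), and with that array as line 1 the median stayed at -0.50 but the call was lost (adjusted p = 0.200). Replicates of COR15A spread widely, from 1299.6 to 1840.0 in the control and from 559.0 to 819.9 in line 4. In a list of clock-regulated genes written after these values were seen, COR27 and COR28 (AT4G33980) fell by 0.99 and 0.80 in line 4 (adjusted p = 9.9e-05 and 0.00184) and FITNESS (AT1G07050) by 1.05 (0.000397). The other 3 measured genes of that list did not pass, with RVE6 (AT5G52660) at -0.40, RVE5 (AT4G01280) at 0.09 and GI at -0.05.

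Other lists were mixed or barely covered. In the calmodulin and touch list, CML42 rose by 0.53 ± 0.10 and CML23 fell by 1.24 ± 0.15, while CML38 differed by 0.10, with 2 passing when adjusted over the list alone, and camera gave an adjusted p of 0.896. Of the 6 measured genes of wall loosening, XTH19 rose by 1.76 ± 0.20 and XTH18 by 0.37, both for enzymes that cut and rejoin xyloglucan, whereas the expansin genes EXPA8 and EXPA15 fell by 0.49 and 0.37, with EXPA4 at -0.36 and XTH16 at -0.21 not passing; 5 passed when adjusted over the list alone and camera gave an adjusted p of 0.896. In the auxin list, 3 of 4 measured genes passed over all probe sets and 4 when adjusted over the list alone. GH3.3 rose by 0.53, WES1, which like GH3.3 encodes an auxin-conjugating enzyme, fell by 0.61 and the root regulator LBD16 fell by 0.79, with IAA29 at -0.61 (adjusted p = 0.143), and camera gave an adjusted p of 0.385. UGT74B1, an enzyme of glucosinolate synthesis, rose by 0.45, with BCAT4 at -0.14 and AT2G31790 at -0.09, so that 1 of 3 passed over all probe sets and when adjusted over the list alone, and camera gave an adjusted p of 0.896. None of the 6 photosynthesis genes passed, with a median of -0.20 (camera adjusted p = 0.176), nor did any of the 3 flavonoid genes DFR, UF3GT and UGT78D2, with a median of -0.14 (camera adjusted p = 0.896). The photosynthesis median was -0.33 without control replicate 2, -0.081 without control replicate 1 and -0.035 after quantile normalization. With the array of conflicting labels as control the list passed in camera at the preset correlation (adjusted p = 0.0290). With an estimated correlation its adjusted p was 0.907 in the fit of all 5 arrays and 0.782 with that array as control. No list passed with an estimated correlation, so that test cannot decide here either. Lists with 1 or 2 measured members were not given a list test. In the salicylate and systemic defence list both measured members rose, GRX480, a glutaredoxin that binds TGA transcription factors, by 1.76 ± 0.16 and SAG101, which acts in immune signalling, by 0.91 ± 0.18 (adjusted p = 0.000145 and 0.00985), and these were 2 of the 22 genes of the list. In the list of early defence, WRKY22 fell by 0.44 and WRKY53 was at +0.42 (adjusted p = 0.0576; both passed when adjusted over the list alone). EIN3, RTE1, GID1A, GID1C, GI, the root hair expansin genes EXPA7 and EXPA18, the guard cell gene FMA and ATHSP22.0 gave differences between -0.37 and 0.33, none passing.

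The labels give both transgenic lines the same modification, so their 3 arrays were also set against the control as a single group. No gene passed this test. The closest named rises were of AT2G21640, a marker of oxidative stress, with a mean difference of +1.55 ± 0.16 (SE, n = 3 against 2, limma adjusted p = 0.127), and of AT1G33790, a jacalin lectin family gene, at +1.32 ± 0.15 (0.127). AT4G17070 (+1.18), AT3G25150 (+4.56), AT2G45010 (+1.06), AT2G20390 (+0.87), AT1G69760 (+0.84), AT1G79470 for inosine monophosphate dehydrogenase (+1.04), AT4G15010 (+1.91), AT5G22580 (+1.304), TRI (+0.97) and AT3G13940 (+0.74) had adjusted p from 0.142 to 0.199. On the lower side the protein phosphatase 2C gene AT3G05640 stood at -1.27 ± 0.15 (0.127), with 34.4 and 40.8 units in line 4 and 35.6 in line 1 against 92.9 and 85.0 in the control. AT4G38080 (-0.99), AT1G01240 (-1.07), AT4G33960 (-0.73), the AP2/ERF factor gene AT1G19210 (-1.18), AT3G07350 (-1.14), AT5G43520 (-0.86), AT2G16660 (-0.89), AT1G10640 (-1.28), AT1G75710 (-0.75), the cyclophilin gene AT2G21130 (-0.59) and CML23 (-1.48) also lay below both control arrays on all 3 transgenic arrays without passing. The naming rule requires all 3 arrays beyond both controls on 1 side, which held at 4761 of all 13647 probe sets. The array with conflicting labels read 50.0 units for AT2G21130, against 401.7 and 363.1 in the control, and with it as control that gene's direction turned. For AT1G01240 it read 232.1, above both controls (135.9 and 155.9).

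With limma, 0 of 13647 probe sets passed an adjusted p of 0.05, and 1770 had an unadjusted p under 0.05. When the same arrays were fitted as 3 groups and the mean of both lines was set against the control, so that the difference between the lines was not part of the error, 2095 passed, and without the line 1 array, which leaves line 4 alone against the control, 2127 passed. Camera called the cold response list (median -1.04, adjusted p = 0.00277) and the nuclear photosynthesis list (median -0.22, adjusted p = 0.00457) as lower, and neither passed with an estimated correlation (adjusted p = 0.825 for each). No member of either list passed over all probe sets, and 2 of the cold response genes but 0 of the photosynthesis genes passed when adjusted over the list alone, as did 1 gene each of the calmodulin and touch list and the early defence list.

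Line 1 was represented by 1 array, so its differences from the control have no replicate check and are given by size, without a p-value. Its largest named difference upward was again AT3G25150, at 144.4 units (+4.75), followed by AT1G50040 (+2.61), QQS, an orphan gene linked to starch content (+2.59), AT3G02480 of the late embryogenesis abundant family (+2.13), AT5G62280 (+1.87) and the RNA-binding protein gene AT1G22330 (+1.87). With a pseudocount of 10.3 these were 3.22, 2.21, 2.22, 1.79, 1.47 and 1.52, and AT3G25150 stood at 3.70 or 5.80 when either control array was left out. The array with conflicting labels read 25.7, 29.1, 83.2, 11.1, 405.2 and 39.8 units for these 6 genes, which for AT3G02480 is below both control arrays (38.6 and 21.8) and for AT1G50040 between them (21.1 and 31.3). With that array as line 1 AT3G02480 stood at 0.37 and AT5G62280 at 3.06, and with it as control AT5G62280 stood at 0.46. Downward, the AP2/ERF factor gene AT5G52020 read 1.2 units against 74.6 and 97.6 in the control (-6.15), the VQ motif gene AT2G22880 read 2.2 against 95.3 and 121.8 (-5.61), and AT3G01830, an EF-hand calcium-binding protein gene, read 2.1 against 51.6 and 56.4 (-4.68). AT4G37290, the matrix metalloproteinase gene AT1G24140 and AT3G60420 followed at -4.34, -4.05 and -3.93. These line 1 values lie near the floor, and with the pseudocount of 10.3 the 6 differences were -3.06, -3.24, -2.37, -2.86, -2.28 and -1.81.

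Genes of the cold response and of the calmodulin and touch lists were low in line 1. COR15A read 155.6 units (-3.31), COR15B 402.2 (-1.86), STZ, a zinc finger gene of salt and cold responses, 237.0 (-2.71), LTI30 284.3 (-1.60) and COR47 1103.5 (-0.79), and the list median of -1.86 lay below all 10000 random lists matched on mean expression. CML38 (-2.05) and CML23 (-1.95) were low and CML42 was at +0.06, and that list's median of -1.95 also lay below all 10000 random lists. These ranks describe 1 array and take genes as unrelated. In both replicated fits the cold response list lost its call with an estimated correlation, where no list passed and the test cannot decide. On the array with conflicting labels COR15A and STZ read lower still, at 45.7 and 87.0. The photosynthesis list (median -0.24) lay at percentile 5.65, the wall loosening list (0.17) at 81.9, the auxin list (-0.003) at 42.0, the glucosinolate list (-0.16) at 17.7 and the flavonoid list (0.04) at 52.1. XTH18 (-1.62) and WRKY53 (-1.98) were also low.

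**Figure D2:**
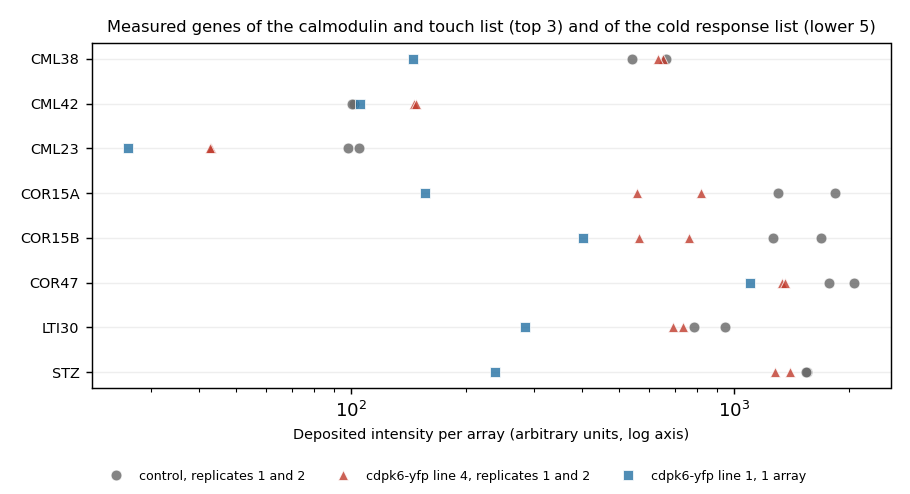
Deposited intensity on a log axis for the measured genes of the calmodulin and touch list and of the cold response list, with a circle for each control array, a triangle for each line 4 array and a square for the line 1 array. COR15A reads 1840.0 and 1299.6 units in the control, 559.0 and 819.9 in line 4 and 155.6 in line 1.

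By size alone, 555 probe sets lay at least 2-fold from the control mean and outside both control arrays in line 1, 152 of them higher and 403 lower. At 4-fold there were 8 higher and 99 lower, and the array with conflicting labels lay below both control arrays at 96 of these 99, and at 36.6% of all probe sets. It lay above both at 128 of the 152 that were 2-fold higher, at 5 of the 8 that were 4-fold higher and at 46.0% of all probe sets. The same rule gave 299 probe sets in line 4, 221 higher and 78 lower, and the control arrays themselves were 2-fold apart at 74 probe sets. The line 1 count was 2528 with no filter on dim probe sets and 258 when the array with conflicting labels was counted as control.

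Finally, the differences of both lines from the control were compared with each other. AT3G25150 was high in both lines, and COR15A, COR15B and CML23 were low in both. AT3G60420 and AT3G01830 went opposite ways, at +3.83 and +1.66 in line 4 and at -3.93 and -4.68 in line 1. Among the 220 rises of line 4 over 2-fold, line 1 lay outside both control arrays on the same side at 83, on the opposite side at 95 and within their range at 42, and the median difference was 1.44 in line 4 and -0.03 in line 1. Among the 77 falls over 2-fold, line 1 lay on the same side at 61, on the opposite side at 9 and within at 7, with medians of -1.15 and -0.59. Simulations held line 1 unchanged, changed line 4 by its estimate where called, and had simulated controls shared by both lines. There line 1 lay on the same side at 37.3% of the rises and 41.5% of the falls (28.0 to 55.1 over 100 draws). The observed shares were 37.7% and 79.2%. On the opposite side the simulated share of the rises was 29.4% (22.7 to 36.1), where 43.2% was observed. The measured line 1 array lay outside both control arrays at 10827 of all 13647 probe sets, whereas the simulation holds line 1 unchanged. An unchanged array would also lie outside 2 others at most probe sets, and this count was not split by side. An excess over the simulation therefore need not be particular to the line 4 changes.

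**Figure D3:**
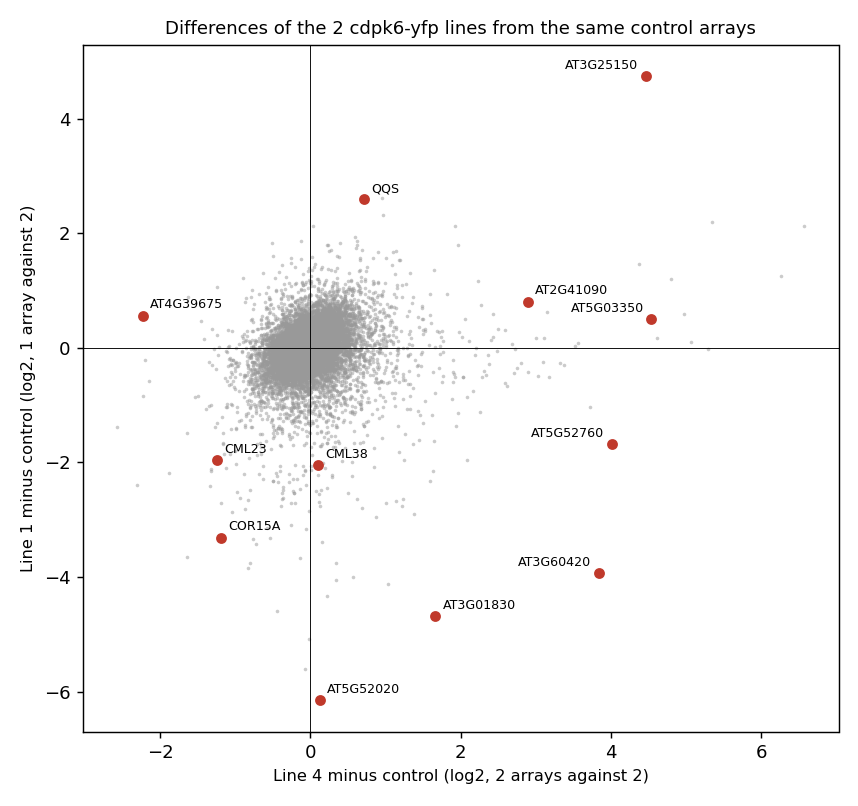
Log2 difference of line 4 from the control on the horizontal axis and of line 1 from the control on the vertical axis for 13647 probe sets, with 12 named genes in red. AT3G25150 lies at 4.46 and 4.75, AT3G60420 at 3.83 and -3.93.

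Across probe sets, Pearson's r between both sets of differences was 0.214 and Spearman's rho 0.335. Unchanged groups simulated with controls drawn anew and shared by both lines gave 0.408 and 0.382. That simulated r comes from the shared controls alone. Changes particular to 1 line lower r and the simulation holds none, so the lower observed r cannot decide how far the lines agree. The covariance was 0.0419, beside 0.0108 in the simulation. All simulated arrays were drawn with the spread that limma moderated across the groups. The measured control replicates differed with an SD of 0.266 and the line 4 replicates with an SD of 0.201. The simulated covariance from shared controls may thus be too small, and the gap does not measure how far the lines agree. The same sign was seen at 62.5% of probe sets, beside 63.4% simulated. By the 2-fold rule, 19 probe sets were higher in both lines and 28 lower in both, where independent lists would share 2.46 and 2.30 and the simulation gave at most 2 and 1. A further 30 were higher in line 4 and lower in line 1, where independent lists would share 6.53 and the simulation gave 0. At 1 probe set line 4 was lower and line 1 higher (0.869 for independent lists). The simulation holds both lines unchanged, so its counts do not show how many changed probe sets would overlap. The 2 control arrays were not split between the lines, so part of the agreement in direction may come from the shared controls. Pearson's r was 0.358 with no filter on dim probe sets and 0.0975 when the array with conflicting labels was counted as control.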

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

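Of the tests below, the one of clock genes in line 1 was fixed before its result was seen, except that GI had been seen, and the others, with the comparison of sides, were chosen after the results they bear on were seen.

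At some of the genes named, the line 1 array and both line 4 arrays lay beyond the control arrays on opposite sides. The difference between the lines counts as not tested, because a limma fit of it, with 2525 calls, was run and then set aside, since line 1 is 1 array and its line and its pool of plants cannot be separated. Over all probe sets there were 2219 such cases, 27.0% of the 8207 where both line 4 arrays lay beyond both controls. In simulations with line 1 unchanged the same share was 20.1% (18.8 to 21.7 over 100 draws) with line 4 unchanged too, 24.7% (23.2 to 26.5) with line 4 changed where called and 29.1% (27.8 to 30.2) with line 4 changed everywhere by its estimate. Of all probe sets these cases were 16.3%, where 5 arrays with no change give 6.67%. The observed share thus lies above or below the simulated one according to how much of line 4 is taken as changed. Among the 102 genes taken by the naming rule, the gene lists or the clock list there were 19 such cases. At 13 of them line 4 was higher and line 1 lower than the control, with log2 differences of 3.83 and -3.93 for AT3G60420, 4.01 and -1.68 for AT5G52760, 1.66 and -4.68 for AT3G01830, 2.90 and -0.42 for AT1G35710, 2.71 and -0.43 for CHI, 2.62 and -0.66 for RING1, 2.59 and -0.62 for AT5G52810, 1.76 and -0.60 for GRX480, 0.45 and -0.16 for UGT74B1, 0.42 and -1.98 for WRKY53, 0.37 and -1.62 for XTH18, 0.34 and -4.05 for AT1G24140, and 0.22 and -4.34 for AT4G37290. At 6 line 4 was lower and line 1 higher, with -2.23 and 0.56 for AT4G39675, -1.45 and 0.46 for AT4G15690, -1.24 and 0.22 for AT3G20340, -0.61 and 0.80 for IAA29, -0.49 and 0.22 for EXPA8, and -0.36 and 0.51 for EXPA4.

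The 99 probe sets that were at least 4-fold lower in line 1, COR15A and AT3G01830 among them, had a median difference of -2.51 there, on an array that, like the array with conflicting labels, also read high for 5S ribosomal RNA. An array of low signal stays open. Line 4, whose spike-in controls also read below the control arrays (median -0.35 and -0.36 against -0.26 in line 1), had a median of -0.21 at these probe sets. This cannot decide, because all arrays had been scaled to a common trimmed mean. A low spike-in reading after that scaling does not mark an array as one of low signal. A harvest at another time of day is argued against by 6 measured clock genes, whose median absolute difference in line 1 was 0.211. FITNESS was at -0.63, RVE6 at -0.33, COR27 at -0.27, COR28 at -0.15, GI at -0.10 and RVE5 at 0.09. A small shift in time could be missed, since RVE5 and RVE6 differed little even on the array with conflicting labels (0.42 and -0.13). A difference in handling or growth of a single pool stays open, because the array with conflicting labels had a median of -3.03 at the same probe sets and of -2.89 against line 4, where no control enters, and lay below both controls at 96 of 99 (36.6% of all probe sets). If that array is line 1 it repeats the falls, and if it is a control it shows them without the transgene, so the line and the pool cannot be told apart.

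The 220 rises of line 4 over 2-fold had a median of 1.44. The high scanner background of control replicate 2 is argued against, since a fit without it, with probe sets called anew, gave 281 rises over 2-fold, 207 of them among the 220. A transgene effect of equal size in both lines would raise line 1 too, where the median at these rises was -0.028. Line 1 is 1 array whose line and pool cannot be separated, so this median cannot exclude such an effect. At the 77 falls over 2-fold line 1 lay on the same side at 61. An effect that differs with the level of the transgene, which was not analysed here, was not tested. A harvest at a different time of day stays open, as does a difference in RNA quality, which was not tested (actin 3′/5′ ratio 3.19 and 3.48 in line 4, 4.27 and 4.30 in the control). The median absolute difference of the 6 clock genes in line 4 was 0.602, at percentile 99.8 of 10000 random sets, with COR27, COR28 (AT4G33980) and FITNESS (AT1G07050) at -0.99, -0.80 and -1.05 (limma adjusted p = 9.9e-05, 0.00184 and 0.000397) but RVE6, RVE5 and GI at -0.40, 0.09 and -0.05, none passing.

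On some arrays ribosomal RNA, which is outside the comparisons, gave signal above the control arrays. The probe set for 25S ribosomal RNA read 282.1 and 277.2 units on the control arrays, 275.4 on line 4 replicate 1, 915.9 on line 4 replicate 2, 1073.1 on line 1 and 2189.3 on the array with conflicting labels. The probe set for 5S ribosomal RNA read 12.7 and 16.1 on the control arrays, 8.2 and 10.4 on the line 4 arrays, 73.2 on line 1 and 83.2 on the array with conflicting labels.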

How the results depend on the processing

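The choice that moved most results was the place of the array with conflicting labels. With it as control, line 4 had 88 calls (90.9% higher, against 52.3% in the main setting), both lines 1, the line 1 count by size was 258, r between the lines 0.0975, AT4G27657 in line 4 stood at 0.066 and the cold response median at 0.50. With it as line 1, line 4 had 183 calls (82.0% higher) and 0 lists passed. All 88 and 183 calls were among the 2111. Causes were not tested. With no filter on dim probe sets, line 4 had 1256 calls (59.0% higher), line 1 a count of 2528 and r was 0.358, and without a variance trend line 4 had 1116. For both lines together, 0 calls became 4 with quantile normalization, 3 with the filter at 60%, and 2095 as the mean of both lines in the fit of 3 groups. Without line 1 only line 4 is left against the control, with 2127 calls. A limma test of the single line 1 array, assumed to vary like the other groups, called 2244 probe sets, and with the conflicting array as a line 1 replicate 516 (155 higher, 361 lower); the former cannot separate line from pool. For the gene lists, 1 passing list became 0 with fry and 0 with an estimated correlation, a test that could not tell the lists apart. Quantile normalization, equal array medians, the 60% filter and the pseudocount left the line 4 count between 1918 and 2160.

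With each replicate left out in turn, which leaves a single array assumed to vary like the other groups, line 4 had 1026 to 2035 calls, the line 1 count was 544 to 650, r was 0.190 to 0.280, both lines together had 0 calls without any control or line 4 replicate (2127 without line 1, as above) and 1 to 2 lists passed. The replicate numbers did not pair the arrays (correlation of the deviations -0.075 across probe sets), and with the replicate number as a block 2638 probe sets were called, 2060 of them shared with the fit without it. Of the named genes' values under alternatives, 282 for line 4 kept direction and call, 32 lost the call, 14 of these with the conflicting array as control and 11 with it as line 1, and 1 reversed. For both lines, where no named gene passed in the main setting, 271 values stayed without a call, whatever their direction. The other 22 passed without line 1, where line 4 alone is compared. For line 1, 98 stayed close and 21 moved. Of list values, 86 kept their call or stayed without one, 2 gained a call, 1 lost it and 1 reversed. For both lines and for lists, a change of direction was counted only where a call was present, so values without a call may have turned. Alternatives for the CDPK6 transcript were not run, since no probe set was named as it. Values near the floor limit the folds of dim genes in line 1.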

Other observations

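The tests and gene families in this part were chosen after the data were seen. Gene families read from the letters of the symbols, 31 with at least 5 measured probe sets, gave no call in line 4 with camera (smallest adjusted p = 0.211). The closest were 8 cytochrome P450 probe sets (median 0.24, 2 of them higher and 0 lower), 5 tubulin probe sets (median -0.28, 0 higher and 2 lower, both at an adjusted p of 0.211) and 6 expansin probe sets (median -0.33, 0 higher and 2 lower, adjusted p = 0.225). In line 1 the 8 U-box ubiquitin ligase (PUB) probe sets had a median of -0.51, at percentile 0.05 of random lists, with 6 below both control arrays. Transcripts encoded in the plastid, 69 probe sets, had a median of -0.01 in line 4, 0.02 in line 1 and -0.19 on the array with conflicting labels.

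The array with conflicting labels differed more from every other array than the grouped arrays did from the control. It lay above both controls at 6273 probe sets and below both at 4991, and correlated at 0.896 and 0.888 with the controls, 0.872 and 0.875 with line 4 and 0.931 with line 1. In the auxin list IAA29, GH3.3 and WES1 read 425.2, 322.4 and 626.0 units there, above every other array, while LBD16 read 51.7, within the control values. In the wall loosening list EXPA4, EXPA8 and EXPA15 read 248.7, 678.7 and 140.5, above every other array, while XTH16 and XTH18 read 196.8 and 97.9, below both controls, and XTH19 read 30.2, within the control values. COR15A read 45.7 units, STZ 87.0 and CML38 18.1. At the 220 rises of line 4 its median difference from the control was -0.09.

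Clock-regulated genes set that array apart. COR27, COR28 (AT4G33980) and FITNESS (AT1G07050) differed from the control mean by -5.71, -6.04 and -5.17 and GI by -1.94, while RVE5 (AT4G01280) and RVE6 (AT5G52660) differed by 0.42 and -0.13. Their median absolute difference was 3.56, above all 10000 random sets of like mean expression, beside 0.28 for all probe sets. A harvest at another time of day is a candidate explanation that these values meet, as a hypothesis found on the same data. Cold, light or age were not tested. COR27 and COR28 are by name cold-regulated too, and COR15A of the cold response list read 45.7 units there against 1840.0 and 1299.6 in the control. The values thus do not separate time of day from cold. Another control pool grown and harvested like the other 2 is argued against by its correlation of 0.888 with control replicate 2, where the controls correlated at 0.983. Its genotype cannot be read from these values.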
